A study of Mus musculus with 6 samples.

How the data were processed

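RNA was measured in 6 libraries of mouse bone marrow-derived macrophages, 3 from untreated control cultures and 3 from cultures given polystyrene micro- and nanoplastics (MNP). Per the labels, total RNA went into libraries made with the CORALL RNA-seq V2 kit, which primes along whole transcripts. The deposited files hold whole-number counts per gene symbol, 1 file per library, for 40213 genes, of which 28815 had a count in any library. Per the submitters' processing notes, fastp, STAR, Salmon and GATK and the mouse build GRCm39 were used, with no role or version stated for any tool. The gene annotation, the strand setting, the use of molecular identifiers and any rounding of Salmon estimates to whole counts are not given in the sources used here. Without a stated strand setting, the deposited counts of a gene and of an antisense or overlapping gene cannot be separated, and counts of near-identical gene copies depend on how shared reads were assigned. The 3 deposited counts of the structural RNA Rn7s2 in the MNP libraries end in 0, as if printed with limited precision.

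Groups and replicate numbers came from the sample titles. The labels do not say whether replicates were separate cultures or animals, so p-values of single genes measure only the spread between these samples, which could be technical. Before replicates were averaged, each pair within a group was compared over genes with at least 10 counts, and chi-square per degree of freedom ran from 6.65 to 17.6, so no pair looked like a single library deposited again. Library totals ran from 20262859 to 23042146 counts, so that 1 count was worth 0.0434 to 0.0494 CPM (counts scaled to a common library size) and 3 counts 0.130 to 0.148 CPM.

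Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization factors, the default expression filter, which left 12893 genes, and the quasi-likelihood F test for MNP minus control. P-values were adjusted by the Benjamini-Hochberg method, a gene was called changed at an adjusted p under 0.05, and the standard error (SE) was taken as the absolute log2 fold change over the square root of F. CPM values are scaled by the TMM factors and given as mean ± SD of 3 samples. The 32 gene lists and 12 lists of markers of other cell types were written before the data were examined, and were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists of each kind with at least 5 tested members. Of the marker lists, 5 had that many. At a preset correlation, camera compares the genes of a list with all other tested genes. Its p-values then take genes, not the 6 samples, as the units, so very small ones do not measure the spread between samples. Within each list, p-values were also adjusted over the list alone.

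The genes named in the text follow a rule written before the data were examined. It takes the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 5 CPM, no overlap between the groups and a gene name; up to 4 called members with the smallest p of each list that passed or had at least 3 called members; and, for the title of the series, Gclc, Gclm, Gss, Gsr, Slc7a11, Gpx1, Gpx4 and Chac1. A further 23 genes were chosen after their values were seen and are identified as such where they are named. Not every gene that the rule takes is reported here.

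The same steps were tested on simulated counts for the 12893 genes, drawn from the means and library sizes of this comparison with 200 changed genes. None of these was among the most weakly expressed genes, and they were far fewer than the 2250 called in the real data. The test recovered 70% of genes changed 1.5-fold and 91% of those changed 2-fold, 9.04% of its calls were false, and 0 of 31 unchanged lists were called. Each simulated gene was drawn independently and the unchanged lists held random genes. The list result therefore does not cover lists whose genes vary together. In the real data the estimated correlation was 0.43 for the interferon response and 0.77 for mitochondrially encoded genes. Alternatives were other scalings (RLE, upper-quartile, library totals), no filter, a stricter filter, a block for the replicate number, DESeq2 1.42.0, limma-voom, stricter thresholds, omission of mitochondrial and the most abundant genes, omission of each library, and for lists an estimated correlation, fry, ranks and omission of genes held by several lists. A correction for GC content and transcript length and the omission of structural RNA genes were added after seeing the data, as were 9 further gene lists. GC content and length came from GENCODE annotation of an older mouse build, matched by gene symbol for 93.4% of tested genes, and no coordinates were used.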

Results

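Bone marrow cells of C57BL/6 mice were grown with macrophage colony-stimulating factor (25 ng/ml) and 10% serum for 4 days, which gives bone marrow-derived macrophages, and were then plated. In 3 samples the cells received polystyrene micro- and nanoplastics (MNP, 50 µg, volume not stated) for 24 h, and 3 control samples received none. Transcripts were counted by RNA sequencing. The control libraries held 20262859, 22214140 and 23042146 counts in all and the MNP libraries 21283713, 22700499 and 21855903. A count was present for 24062, 20935 and 20222 genes in controls 1 to 3 and for 18672, 18655 and 18240 genes in MNP samples 1 to 3. MNP sample 1 stood apart in the structural RNA Gm26917, which took 1.02% of its counts against 0.25% to 0.44% in the other 5 libraries. Mitochondrial ribosomal RNA took 0.115% of its counts, against 0.022% to 0.033% in the other 5 libraries.

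The comparison of MNP with control samples addresses which transcripts differ in macrophages exposed to plastic particles, and the series title directs it to glutathione metabolism. After MNP treatment, Gclm, Gclc and Slc7a11 of glutathione synthesis and all 30 tested NRF2 targets rose, and all 43 tested interferon-response genes and 8 of 11 MHC class II genes fell. Of 12893 genes tested, 2250 (17.5%) changed, 1174 of them higher and 1076 lower in MNP samples. A change of at least 2-fold was found for 461 genes, of which 166 were higher and 295 lower. The first principal component held 47.3% of the variance and placed the controls between -34.4 and -22.3 and the MNP samples between 26.7 and 28.8. The second held 17.8% and set MNP sample 1 (32.6) apart from MNP samples 2 and 3 (-11.3 and -18.9).

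Both subunits of glutamate-cysteine ligase, the rate-limiting enzyme of glutathione synthesis, rose. Gclm, the modifier subunit, went from 49.7 ± 3.31 to 351 ± 22.4 CPM (7.06-fold, log2 fold change 2.82 ± 0.07 SE, edgeR adjusted p = 7.35e-11). Gclc, the catalytic subunit, went from 57.1 ± 2.41 to 165 ± 10.1 CPM (2.89-fold, log2 1.53 ± 0.06). Slc7a11, the cystine importer that supplies cysteine, rose 4.92-fold from 34.4 ± 3.40 to 169 ± 6.44 CPM, and Gsr, which reduces oxidized glutathione, rose 2.44-fold from 65.2 ± 3.53 to 159 ± 14.0 CPM. The glutathione exporter Abcc1 rose 2.37-fold. The count of Gss, glutathione synthetase, was 2.87-fold higher (5.82 ± 0.789 to 16.8 ± 2.17 CPM), but Gss overlaps the antisense gene Gssos2, whose count was 45.4-fold higher (1.20 ± 0.699 to 53.6 ± 0.910 CPM), and without a stated strand setting the share of each is uncertain.

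Glutathione-consuming enzymes did not all move alike. Gpx1, the abundant selenium-dependent glutathione peroxidase, fell 2.38-fold from 313 ± 23.7 to 132 ± 4.57 CPM (log2 -1.25 ± 0.06, edgeR adjusted p = 2.83e-08). Gpx4, which reduces lipid hydroperoxides, did not pass (81.3 ± 2.88 and 91.0 ± 1.17 CPM, log2 0.16 ± 0.06, edgeR adjusted p = 0.0739). Chac1, a glutathione-degrading enzyme, was near the counting limit at 0.171 ± 0.194 and 0.645 ± 0.228 CPM (edgeR adjusted p = 0.116). Among transferases and related enzymes, Gsta3 rose from 1.31 ± 0.248 to 26.3 ± 1.20 CPM (log2 fold change 4.32 ± 0.15), Prdx6 4.57-fold, and Esd, which hydrolyses S-formylglutathione, 2.34-fold.

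**Figure D1:**
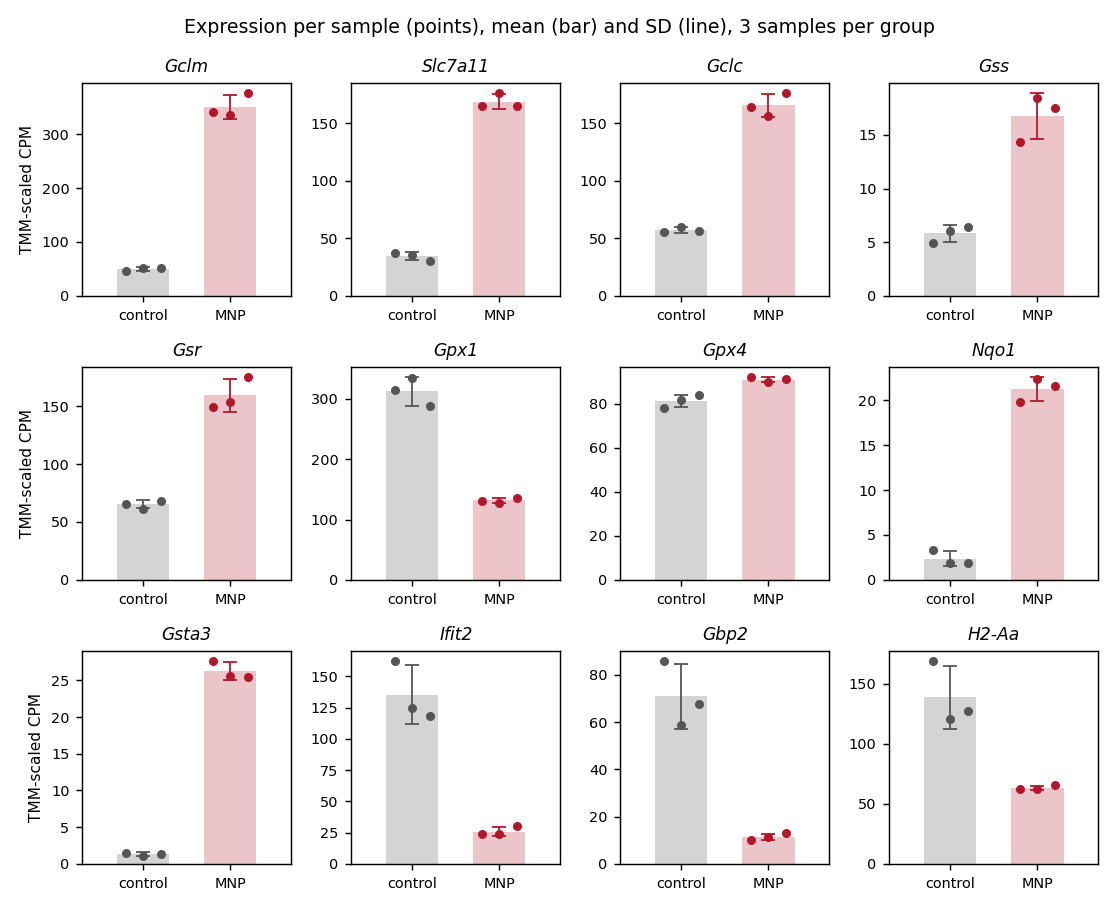
Counts scaled to library size by TMM factors, as CPM (vertical axis, from 0) of 12 genes in the 3 control and the 3 MNP samples, with points for samples, bars for means and lines for the SD. Gclm rose from a mean of 49.7 to 351 CPM, Gpx1 fell from 313 to 132 CPM and Ifit2 fell from 135 to 25.7 CPM.

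Of 23 tested genes for glutathione synthesis and turnover, 9 rose and 0 fell (10 and 0 when adjusted over the list alone), with a median log2 fold change of 0.19 (camera adjusted p = 1.83e-05, and adjusted p = 0.105 with an estimated correlation). Of 24 transferases and peroxidases, 9 rose and 3 fell (12 and 3 when adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.00881, and adjusted p = 0.116 with an estimated correlation). The synthesis list's median was 0.34 without control 3 and 0.29 without MNP sample 1. Neither list passed once genes held by more than 1 list were left out (adjusted p = 0.164 and 0.243). The synthesis list shares 5 tested members with the NRF2 target list, Abcc1, Gclc, Gclm, Gsr and Slc7a11, and the transferase list shares 3.

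NRF2 is the transcription factor that drives antioxidant and detoxification genes, and all 30 tested genes of its target list rose (30 when adjusted over the list alone), with a median log2 fold change of 1.23. The quinone reductase Nqo1 went from 2.35 ± 0.832 to 21.2 ± 1.35 CPM (9.11-fold), the sulfiredoxin Srxn1 from 113 ± 8.88 to 444 ± 29.3 CPM (3.94-fold) and the peroxiredoxin Prdx1 from 2168 ± 55.6 to 5672 ± 176 CPM (2.62-fold). Malic enzyme Me1, an NADPH source, rose 5.25-fold and heme oxygenase Hmox1 1.59-fold. The list passed camera with adjusted p = 2.34e-32, but adjusted p = 0.0751 with an estimated correlation. Outside the list, catalase (Cat) rose 3.48-fold from 290 ± 13.0 to 1009 ± 47.5 CPM and superoxide dismutase Sod1 1.48-fold, while Selenop, a secreted selenium carrier, fell 3.65-fold from 1530 ± 264 to 420 ± 6.51 CPM and Selenow fell 3.04-fold. The list of other antioxidant enzymes that holds these 4 genes did not pass, with 3 members higher and 2 lower of 19 (median 0.03, camera adjusted p = 0.393), except with no filter (0.09, adjusted p = 0.0190) and with fry (adjusted p = 0.0147), and its median was -0.06 with library totals alone.

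Other large increases fell outside these pathways. Ednrb, an endothelin receptor, rose 7.43-fold from 12.3 ± 1.98 to 91.7 ± 19.6 CPM, and Cdkn1c, a cyclin-dependent kinase inhibitor, rose 7.06-fold from 33.5 ± 10.7 to 236 ± 13.1 CPM. The protease inhibitor Serpinb9b rose 6.93-fold, the ubiquitin hydrolase Uchl1 6.16-fold and the protein C receptor Procr 5.31-fold. With Gssos2, Gsta3, Nqo1, Gclm and Me1, these were the 10 largest increases under the naming rule.

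The interferon response moved the other way, and all 43 tested genes of its list fell (43 when adjusted over the list alone), with a median log2 fold change of -1.79. Ifit2, an antiviral effector, went from 135 ± 23.7 to 25.7 ± 3.70 CPM (5.26-fold lower, log2 -2.39 ± 0.12, edgeR adjusted p = 2.83e-08). The guanylate-binding protein Gbp2 went from 70.9 ± 13.8 to 11.5 ± 1.33 CPM (6.16-fold lower), Ifit3 was 5.78-fold lower, Ifi209 4.64-fold lower and Rtp4 4.11-fold lower. The nucleic acid sensor Zbp1 was 6.87-fold lower. The immunity-related GTPase Iigp1, which the list does not hold, had the largest decrease under the naming rule, 21.1-fold, from 9.71 ± 0.234 to 0.455 ± 0.241 CPM. Its MNP values, 0.242 to 0.717 CPM, were near the counting limit, so the size of that decrease is uncertain. Gbp7 and Ifit3b of the list, and Tgtp2, Ifit1bl1 and Ms4a4c outside it, complete the 10 largest decreases, between 5.78-fold and 7.50-fold for these 5. The list passed camera with adjusted p = 1.68e-32, but adjusted p = 0.116 with an estimated correlation. Ifit3, Ifit3b, Tgtp2, Iigp1, Gsta3, Prdx6 and Serpinb9b belong to families of near-identical copies, so their separate counts are uncertain.

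Most members of the 2 antigen presentation lists fell. Of 11 MHC class II genes, 8 fell and 0 rose (8 and 0 when adjusted over the list alone), among them the master regulator Ciita (3.16-fold lower), H2-Aa (139 ± 26.3 to 63.2 ± 1.95 CPM, 2.20-fold lower), H2-Eb1 (2.51-fold lower) and the costimulatory ligand Cd86 (2.41-fold lower). The list's median was -1.0 (camera adjusted p = 6.82e-06, and adjusted p = 0.163 with an estimated correlation). Of 18 MHC class I genes, 12 fell and 0 rose (13 and 0 when adjusted over the list alone), with smaller decreases, such as 1.65-fold for the activator Nlrc5 and 1.60-fold for the peptide transporter Tap1 (median -0.35, camera adjusted p = 4.06e-06, and adjusted p = 0.165 with an estimated correlation). Counts of H2-Q4, 1.88-fold lower, are uncertain because class I genes are near-identical.

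In the lists of inflammatory and alternative activation genes, more members fell than rose. Of 31 NF-kB targets and mediators, 16 fell and 1 rose (18 and 2 when adjusted over the list alone), including the chemokine Cxcl10 (5.15-fold lower), the adhesion molecule Vcam1 (3.84-fold lower), and Il1rn, an antagonist of interleukin 1 (169 ± 9.42 to 78.2 ± 4.31 CPM, 2.16-fold lower). The median was -0.53 (camera adjusted p = 1.33e-05, and adjusted p = 0.105 with an estimated correlation). Of 23 markers of alternative activation, 10 fell and 2 rose (10 and 3 when adjusted over the list alone), with the lectin Clec10a 3.90-fold, the folate receptor Folr2 2.37-fold and the mannose receptor Mrc1 1.91-fold lower (median -0.42, camera adjusted p = 0.000269, and adjusted p = 0.105 with an estimated correlation).

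**Figure D2:**
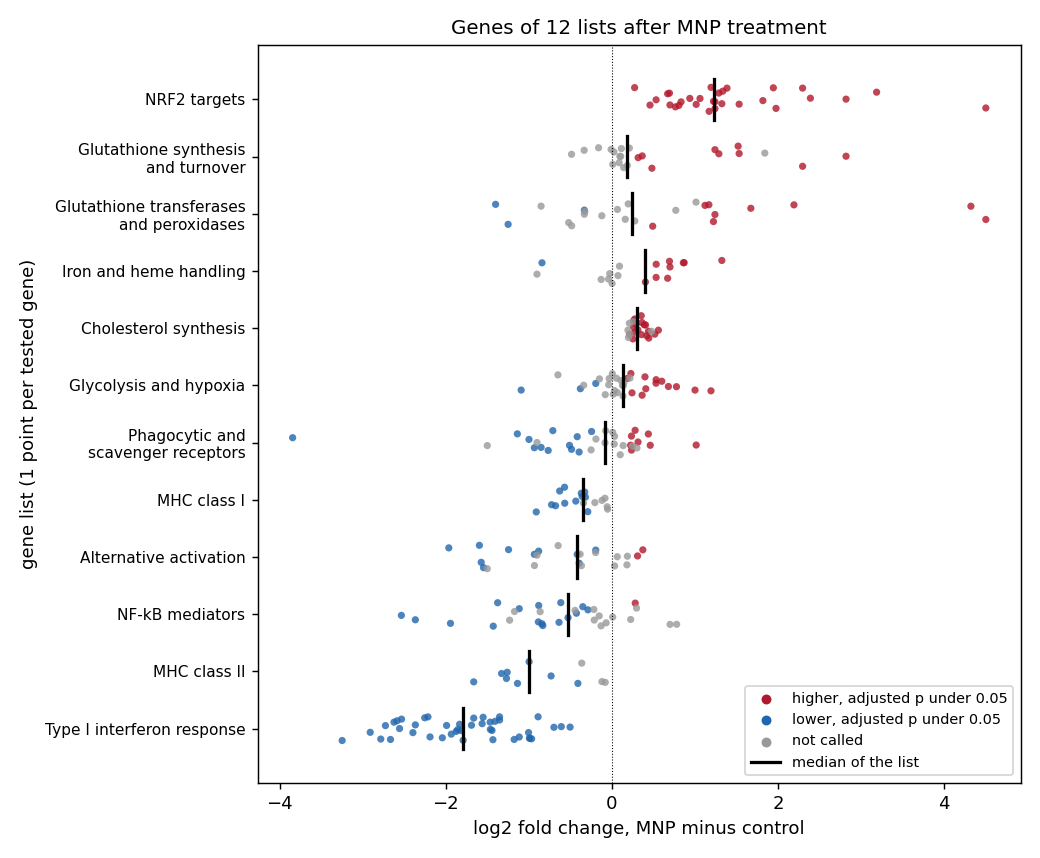
Log2 fold changes of MNP minus control (horizontal axis) for the tested members of 12 gene lists (vertical axis), 1 point per gene, red for genes that rose, blue for genes that fell and grey for genes not called, with a black bar at the list's median. All 30 NRF2 targets lie above 0 with a median of 1.23 and all 43 interferon-response genes lie below 0 with a median of -1.79.

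Some metabolic lists passed and others did not. Of 24 cholesterol synthesis genes, 18 rose and 0 fell (19 and 0 when adjusted over the list alone), with the squalene epoxidase Sqle 1.43-fold higher (median 0.30, camera adjusted p = 7.87e-09, and adjusted p = 0.142 with an estimated correlation). Of 17 genes of iron and heme handling, 9 rose and 1 fell (9 and 1 when adjusted over the list alone), including biliverdin reductase Blvrb (2.51-fold), the metal transporter Slc11a1 (1.82-fold) and the ferritin chains Ftl1 (1.62-fold) and Fth1 (1.45-fold), both of which have many processed copies (median 0.40, camera adjusted p = 0.000448, and adjusted p = 0.105 with an estimated correlation). The NRF2 list, all of whose genes rose, holds 5 of the 17, Blvrb, Fth1, Ftl1, Hmox1 and Slc48a1. Once genes held by more than 1 list were left out, the camera adjusted p of the iron list was 0.0409. Of 33 glycolysis and hypoxia genes, 13 rose and 3 fell (14 and 4 when adjusted over the list alone), with Pkm 1.60-fold, Pgk1 1.52-fold and Aldoa 1.45-fold higher (median 0.13, camera adjusted p = 0.00468, and adjusted p = 0.105 with an estimated correlation). Fatty acid oxidation (2 higher and 1 lower of 22, camera adjusted p = 0.462) and the nuclear-encoded respiratory chain (2 higher and 3 lower of 63, camera adjusted p = 0.474) did not pass, the latter except with no filter (median 0.04, adjusted p = 0.00237).

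Genes of lipid handling split within their list. Of 27 lipid-laden macrophage and LXR target genes, 12 rose and 5 fell (15 and 5 when adjusted over the list alone). The fatty acid receptor Cd36 rose 2.02-fold from 1735 ± 109 to 3508 ± 237 CPM, Mylip rose 2.13-fold, and the desaturases Scd1 and Scd2 rose 2.43-fold and 1.97-fold. Among the 5 that fell were Nr1h3, which encodes LXR alpha (1.85-fold lower), the lipid carrier Apoe (log2 -0.59 ± 0.08) and the cholesterol exporter Abca1 (1.46-fold lower), named after their values were seen. The median was 0.16 (camera adjusted p = 0.0151, adjusted p = 0.304 with an estimated correlation, 0.0546 on ranks and 0.337 once genes held by more than 1 list were left out).

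Receptors that bind particles and debris moved in both directions. Of 33 phagocytic and scavenger receptors, 8 rose and 12 fell (9 and 13 when adjusted over the list alone), with Cd36 higher and Tlr2 (2.20-fold lower), Mrc1 and Msr1 (1.31-fold lower) lower, and the list did not pass (median -0.08, camera adjusted p = 0.194) except with fry (adjusted p = 0.0104). Of 25 genes of monocyte and macrophage identity, 11 fell and 1 rose (11 and 2 when adjusted over the list alone), among them the transcription factor Maf (1.86-fold lower) and the chemokine receptor Ccr2 (1.58-fold lower), while the lectin Clec4d rose 1.53-fold. This list had a median of -0.17 (camera adjusted p = 0.0107, adjusted p = 0.278 with an estimated correlation, 0.118 with no filter and 0.0759 once genes held by more than 1 list were left out). Of 45 cell cycle genes, 4 rose and 3 fell, and the list did not pass (median -0.03, camera adjusted p = 0.946), but it did without control 1 (median -0.14, adjusted p = 0.0275). Its median was positive with no filter and without control 2, control 3 or MNP sample 1, so its direction is not settled.

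Stress-response lists differed in outcome. Of 28 genes of the ATF4 integrated stress response, 6 rose and 1 fell (7 and 1 when adjusted over the list alone), among them Slc7a11, the stress cytokine Gdf15 (2.15-fold) and the mitochondrial folate enzyme Mthfd2 (1.63-fold). The ATF4 list's median was 0.14 (camera adjusted p = 0.00575, adjusted p = 0.150 with an estimated correlation and 0.0459 once genes held by more than 1 list were left out). Of 17 heat shock genes, 5 rose and 0 fell (7 and 0 when adjusted over the list alone), with Dnajb4 1.40-fold and Hsp90ab1 1.21-fold higher (median 0.16, camera adjusted p = 0.0124, and adjusted p = 0.150 with an estimated correlation). The unfolded protein response list (5 higher and 2 lower of 21, camera adjusted p = 0.0613) and the p53 and apoptosis list (4 higher and 3 lower of 23, camera adjusted p = 0.946) did not pass. The unfolded protein response list, with a median of 0.08, passed with no filter (0.10, adjusted p = 0.00280), on ranks (0.08, adjusted p = 0.0347), and without control 1 (0.08, adjusted p = 0.0483), control 3 (0.10, adjusted p = 0.0281), MNP sample 1 (0.08, adjusted p = 0.0472) or MNP sample 2 (0.06, adjusted p = 0.0372). With library totals alone its median turned negative (-0.01). The inflammasome list split, with 7 of 17 genes lower, such as the lipopolysaccharide sensor Casp4 (2.53-fold lower), and 3 higher, such as Nlrp1b (1.86-fold). That list had a median of -0.20 (camera adjusted p = 0.0367, and adjusted p = 0.353 with an estimated correlation) and lost its call in 8 of the other alternatives, among them without control 3 (-0.20, adjusted p = 0.0674), MNP sample 1 (-0.19, adjusted p = 0.0795) or MNP sample 2 (-0.15, adjusted p = 0.110).

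Of 13 mitochondrially encoded genes, 5 rose and 0 fell (9 and 0 when adjusted over the list alone), led by COX1 of the respiratory chain (4688 ± 693 to 6775 ± 506 CPM). The list's median was 0.37 (camera adjusted p = 0.00527, adjusted p = 0.447 with an estimated correlation and 0.150 with fry) and 0.21 without control 1. Mitochondrial transcripts took 2.17% to 3.33% of counts in controls and 3.13% to 3.69% in MNP samples. The other lists that passed were ferroptosis regulators (7 higher and 1 lower of 21), the tricarboxylic acid cycle (4 and 0 of 25), metallothioneins and zinc transport (4 and 0 of 7), endocytosis and actin remodelling (8 and 1 of 32) and complement (2 and 6 of 11), with adjusted p = 0.105, 0.184, 0.142, 0.184 and 0.150 with an estimated correlation. The tricarboxylic acid cycle list's median of 0.08 turned negative with library totals alone, and its call was lost there, as was that of the endocytosis list. The ferroptosis, endocytosis and complement lists did not pass once genes held by more than 1 list were left out (adjusted p = 0.479, 0.0519 and 0.0639), and the endocytosis and complement lists did not pass with the stricter filter (0.0636 and 0.121).

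Some of the tested markers of dendritic cells and of neutrophils fell. Of 11 dendritic cell markers, 6 fell and 0 rose (6 and 0 when adjusted over the list alone), with Irf4 at 8.37 ± 1.39 and 2.81 ± 0.807 CPM and Dpp4 at 1.52 ± 0.338 and 0.205 ± 0.0762 CPM (median -1.50, camera adjusted p = 5.07e-05, and adjusted p = 0.0490 with an estimated correlation). Leaving out 1 library made the decrease smaller each time, with a median of -0.92 without control 2. The marker Bst2 is also an interferon-response gene, and Dpp4 was near the counting limit in the MNP samples. Of 15 neutrophil markers, 7 fell and 1 rose (7 and 1 when adjusted over the list alone), with S100a9 at 106 ± 18.6 and 58.8 ± 6.54 CPM and Ltf 2.33-fold lower, while Mmp8 rose 1.55-fold (median -0.61, camera adjusted p = 0.00348, and adjusted p = 0.182 with an estimated correlation). The other 3 lists with enough tested members did not pass, with medians of -0.92 for megakaryocytes and platelets, -0.81 for stem and progenitor cells and 0.09 for osteoclasts. The megakaryocyte list did pass without control 1 (-0.80, adjusted p = 0.0455), and the stem and progenitor list without control 1 (-0.69, adjusted p = 0.0336) or MNP sample 2 (-0.79, adjusted p = 0.0427). Both also passed with RLE factors, with the replicate block and with fry, and the megakaryocyte list on ranks. With the stricter filter the median of the stem and progenitor list was only -0.06 (camera adjusted p = 0.463).

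The spread between replicates was small, with a biological coefficient of variation of 9.90%, and the 3 values of each group did not overlap for 34.6% of tested genes, where chance gives 10%. In all, 22 of the 32 gene lists passed, 14 upward and 8 downward, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.0751 and 11 lists had an unadjusted p under 0.05. A higher correlation does not account for every loss. The estimates for glutathione synthesis (0.0058) and transferases (-0.019) lay below the preset 0.01. Their unadjusted camera p still rose, from 4.00e-06 to 0.0087 and from 0.0039 to 0.033, so this option changed more than the correlation. With an estimated correlation, camera tests on the few degrees of freedom left by the 6 samples. With the preset it uses those of the genes. The fry test called 23 lists. The balance of higher and lower genes rests on the scaling: 52.2% of changed genes were higher with TMM factors and 28.1% with library totals alone. With library totals the medians of the gene lists were lower, and small ones shifted by over 1.5 times, to 0.10 for glutathione synthesis, 0.15 for transferases, 0.05 for the ATF4 response, 0.07 each for heat shock, ferroptosis and the lipid-laden list, 0.05 for glycolysis, 0.02 for endocytosis and -0.26 for macrophage identity. Of these 9 lists, endocytosis lost its call there. Without MNP sample 2 the count of changed genes was 1471.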

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

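The correction for GC content and length and the omission of structural RNA genes were chosen after seeing the data. The count of 2250 changed genes stayed within 1.5 times under the other scalings, filters and tools, from 2075 with DESeq2 to 2698 with library totals alone, where 757 genes were higher and 1941 lower. At an adjusted p under 0.01 it was 1272 (685 higher, 587 lower), and with at least a 2-fold change 461 (166 higher, 295 lower). Leaving out 1 library gave 1471 (without MNP sample 2) to 2245 changed genes, 793 to 1241 higher and 672 (without MNP sample 2) to 1004 lower, with fewer samples per fit. An estimated correlation left 0 gene lists past the threshold, with unaltered medians of 1.23 for NRF2 targets (adjusted p = 0.0751, from 1.14e-50 to 0.0751 over alternatives), -1.79 for the interferon response (0.116, from 5.28e-42 to 0.116), 0.19 for glutathione synthesis (0.105, from 2.5e-09 to 0.164) and 0.24 for transferases (0.116, from 0.000223 to 0.243 over camera alternatives). With genes of several lists left out, 14 lists passed, and the medians of glutathione synthesis and transferases were 0.10 and 0.13, neither past the threshold. The transferase list also failed under the stricter filter (median 0.15, adjusted p = 0.115) and on ranks (0.24, adjusted p = 0.0752), and the cause was not tested. Leaving out 1 library kept the medians between 1.19 and 1.27 (NRF2) and between -1.83 and -1.59 (interferon), but moved that of glutathione synthesis to 0.34 (without control 3) and 0.29 (without MNP sample 1). Marker lists past the threshold, 2 as reported, numbered 4 with RLE factors, with the replicate block and with fry, 1 with the stricter filter and 1 with an estimated correlation, and 2 to 4 with 1 library left out (4 without control 1). Of the 22 gene lists past the threshold as reported, 12 kept the call in every list alternative run other than the estimated correlation. Over 151 genes named by rule and 19 alternatives, 2673 of 2860 values kept their side of the threshold, 186 no longer passed, 1 newly passed and 0 reversed. The requirement of a 2-fold change alone gave 88 of the 186 losses. For 23 genes chosen later, 417 of 434 values kept their side, 13 no longer passed, 4 newly passed and 0 reversed. Most genes of both sets were picked from these same data for a large change or a small p, or after their values were seen. They tend to lie far from the threshold, so these tallies do not measure how stable the calls of other genes are.

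Over all tested genes, samples with the same replicate number deviated together little (correlations 0.0867, 0.0282 and -0.0218). MNP sample 2 correlated best with control 3 (0.0840), so the numbers were not taken to pair the samples. The mitochondrial share of counts, however, rose with the replicate number in both groups. It was 2.17%, 2.90% and 3.33% in controls and 3.13%, 3.53% and 3.69% in MNP samples, so a pairing is not ruled out. With the replicate number as a block, 2686 genes were called, 1432 higher and 1254 lower. The list of mitochondrially encoded genes then had camera adjusted p = 9.22e-05, against 0.00527 without the block. At this depth and spread, simulated 1.5-fold changes were recovered for 70% of genes, so smaller differences can be missed. The most weakly expressed genes were not among those simulated as changed, so this share does not cover them.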

Other observations

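The lists of NADPH, proteasome, heme, purine, prostanoid, aryl hydrocarbon receptor and selenoprotein genes and the members named from them, Fscn1, Ccr7 and Nfe2l2, the tests on dendritic cell markers and the GC and length correction were chosen after seeing the data. In a list of 16 genes of the pentose phosphate pathway and NADPH supply, 6 rose, 0 fell and 10 were not called, with transaldolase Taldo1 (2.53-fold), Pgd (2.25-fold) and G6pdx (1.78-fold) higher (median 0.08, camera adjusted p = 0.00685, and adjusted p = 0.0916 with an estimated correlation). The NRF2 list holds 5 of these genes. Of 31 proteasome subunits, 14 rose and 0 fell, with Psmb5 1.42-fold and Psmd1 1.37-fold higher (camera adjusted p = 3.45e-07, and adjusted p = 0.0916 with an estimated correlation). Heme synthesis genes numbered 3 higher and 0 lower of 11, led by Alas1, the first enzyme of the pathway (2.22-fold), and the porphyrin transporter Abcb6 (2.20-fold; camera adjusted p = 0.0256, and adjusted p = 0.224 with an estimated correlation). Among 15 purine and folate enzymes 3 rose and 0 fell, with the AMP deaminase Ampd3 2.83-fold higher (camera adjusted p = 0.00413, and adjusted p = 0.0916 with an estimated correlation).

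Prostanoid genes moved both ways, 6 higher and 2 lower of 16 (camera adjusted p = 0.0135, and adjusted p = 0.0916 with an estimated correlation). The prostacyclin receptor Ptgir rose 2.80-fold and the prostaglandin reductase Ptgr1 3.24-fold, while Hpgd, which inactivates prostaglandins, fell 2.92-fold. Of 12 listed aryl hydrocarbon receptor targets 5 were tested, and they did not pass as a list (1 higher and 2 lower, camera adjusted p = 0.358). The higher gene, Nqo1, is also in the NRF2 list, while the receptor's repressor Ahrr was 3.28-fold lower and Tiparp 1.34-fold lower. In the lists fixed beforehand, the matrix protease Mmp12 rose 2.24-fold from 1946 ± 150 to 4359 ± 133 CPM and Mmp14 fell 2.98-fold, and the complement gene C3 fell 1.94-fold and C1qa 1.52-fold. The mRNA of Nfe2l2, which encodes NRF2, did not pass (317 ± 27.7 and 297 ± 10.2 CPM, log2 -0.10 ± 0.07, edgeR adjusted p = 0.359).

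Gpx1 and Selenop were lower in MNP samples, while Cat and the NRF2 targets were higher, and a hypothesis is a lower stability of the selenoprotein mRNAs that are known to decay when selenium is short. In 5 such genes other than Gpx1 and Selenop, which include Gpx3 (2.64-fold lower) and Selenow, the median log2 fold change was -1.40, against 0.06 in 8 less sensitive selenoprotein genes (exact permutation test across genes, two-sided p = 0.0233 over 1287 regroupings; genes are not independent replicates). With Gpx1 and Selenop these genes numbered 6 lower of 7 (camera adjusted p = 2.33e-05, and adjusted p = 0.0842 with an estimated correlation), but the full list of 20 selenoproteins, 3 higher and 8 lower, did not pass (median -0.05, camera adjusted p = 0.245). Msrb1 did not follow (log2 0.22 ± 0.08), Selenot of the less sensitive group fell (log2 -0.47 ± 0.05), and Selenoh lost its call without control 2 or 3 or MNP sample 1 or 2. A GC or length trend was argued against, since its removal moved genes by a median of 0.0047 and at most 0.13, far less than these falls, and the larger of the corrected values for Gpx1 and Selenop was -1.24; selenium and mRNA decay were not measured, so this may equally be lower transcription.

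The fall of the interferon list was weighed against scaling, sequence composition and cell makeup. The highest median over 4 scalings was -1.79, and removal of the GC and length trends, which moved genes by a median of 0.0047 (99th percentile 0.046, at most 0.13), left the median at -1.78, so these trends are far smaller than the fall and the tables argue against both. Fewer dendritic cells in the MNP cultures remain open, since the 10 dendritic cell markers outside the interferon list had a median of -1.51 (all 11 markers -1.50, and -0.92 without control 2), although Fscn1 (-0.10 ± 0.36) and Ccr7 (-0.28 ± 0.40) did not pass and the highest of these markers, Irf4, reached only 8.37 CPM in controls. Of those markers, Irf4 and Cd209a also stand in the alternative activation list, so a lower level in macrophages could give the same values. A like fall of macrophage genes that dendritic cells lack would have gone against this explanation, but such genes were not tested as a set. The macrophage identity list (11 lower and 1 higher of 25, median -0.17) was not sorted by what dendritic cells express. Lower interferon signalling after MNP treatment is the untested biological alternative.

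Weakly expressed genes tended to be lower in MNP samples, with a median log2 fold change of -0.14 in the 2579 tested genes of lowest mean CPM (151 lower and 61 higher). Control 1, which had counts for the most genes, may carry diffuse background reads. Without it the median was -0.061. Olfactory and vomeronasal receptors were taken as a measure of background, without a test that these cells do not express them. They took 85.8 CPM in control 1 (95% counting interval 81.8 to 89.9), against 48.0 to 56.3 CPM in the other 5 libraries. This was 1.52 times the next library and short of the 2 times set for it. In MNP sample 1 the 1150 receptor counts lay on 52 genes. Much of this CPM may therefore not be diffuse, and the ratio cannot decide the question. Of 1479 such receptor genes, 293 had a count in control 1, against 124 and 137 in the other controls and 52 to 63 in MNP samples, which goes with the explanation, but since this number was higher in all controls than in any MNP sample, it cannot be told apart from a difference between the groups. The dendritic cell markers are not part of this trend, since their median lay at percentile 0 of 10000 random lists matched on expression, whose central 95% ran from -0.54 to 0.23. This was not particular to dendritic cells. The percentile was 0 for neutrophil, 0.11 for megakaryocyte and platelet and 0.1 for stem and progenitor markers, but 86.7 for osteoclast markers.

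The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2250 changed genes and the highest of the others 1, so that 1 split, the real one, reached 2250. Every other split mixed control and MNP samples on both sides, which puts the treatment difference into the spread. Few genes could pass there, so those low counts do not show what chance alone gives. The real split gave 22 gene lists, and again only it, 1 of 10, reached 22. The other splits gave 4 to 8 gene lists with at most 1 changed gene, so lists could pass there with almost no gene called. Those splits still hold part of the treatment difference, so they do not count false list calls. The real split gave 2 marker lists, and 2 splits, the real one included, reached 2, the highest of the others.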
